A study of Mus musculus with 14 samples.

How the data were processed

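RNA of sorted leukemic progenitors from 14 mice was profiled by QuantSeq 3′ mRNA sequencing, in which each transcript is read near its polyadenylated end, so that a count does not scale with transcript length. Per the labels' protocols, mice transplanted with I1DN cells received vehicle or AG120 for 5 or 14 days, or AG120 for 28 days followed by relapse, and cells positive for cKit and negative for CD11b were sorted per mouse. Each library was therefore taken as 1 mouse.

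The authors deposited 1 table of raw counts per gene, with 52636 Ensembl gene identifiers in 14 columns, each of which was matched to a library by its name. The submitters' processing notes list bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.1.0, Subread 1.6.3 with its counter featureCounts, R 3.6.2, limma 3.42.2, edgeR 3.28.1 and the genome build mm10. Whether counting used strand, how reads that match several places were treated, and whether molecular identifiers were used are not given in the sources used here. Symbols and positions (GRCm38, the assembly of mm10) came from a gene annotation matched by identifier, which named 52403 of the identifiers; 22670 identifiers had no count in any library. Genes with near-identical copies, such as the globin genes and some histone genes, and genes that overlap others are uncertain, since reads may be split or shared between them.

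Total deposited counts were 6184943 to 7422655 in AG120 day 5, 4995738 to 5357414 in AG120 day 14, 6263518 to 7619764 in vehicle day 5, 5944412 to 7650267 in vehicle day 14 and 5469485 to 8691708 in relapse. The 5 ribosomal RNA gene models held most of them (CT010467.1 20.5%, Gm42418 19.9%, AY036118 19.7%, mt-Rnr2 1.64% and mt-Rnr1 0.692% of all counts), so the usable depth was 1259982 to 3358874 counts. Between 15336 and 19770 genes were detected per library. All were kept in the table, and the scaling factors (TMM, 0.672 to 1.33) took up the difference in composition. Counting error of a gene with few counts is large at this depth, and a gene with 0 counts in a library could have had up to 3 counts; such limits cover counting error only.

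The tests used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr on the group (minimum count 10), which left 11994. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood method (robust, 1 coefficient per group, no other covariate) over all 14 libraries, with 9 residual degrees of freedom, a common dispersion of 0.0291 and a median prior of 7.85 degrees of freedom, so that the groups of 2 shared the estimate of the spread. Comparisons were AG120 minus vehicle at day 5, at day 14 and as the mean of both, the day 14 effect minus the day 5 effect, relapse minus the mean of both vehicle groups, relapse minus the mean of both AG120 groups, and vehicle day 14 minus vehicle day 5. All adjusted p values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested, with 0.05 as the threshold, and "passed" refers to it. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Principal components used the 2000 most variable genes.

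Before the data were examined, the comparisons, the tests, the 32 gene lists from textbook knowledge, the rule for named genes and most of the alternatives were fixed. The lists covered G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, stem and leukemia stem cell genes, primary granule, secondary granule, monocyte, dendritic cell and MHC class II, erythroid, megakaryocyte, mast cell with basophil and eosinophil, B and plasma cell, T and NK cell, and stromal and endothelial genes. They also covered responses to interferon, MAPK and RAS, TNF and NF-kB, TGF-beta and p53, immediate early genes, hypoxia and glycolysis, oxidative phosphorylation, cholesterol, ATF4, the unfolded protein response, lysosome, 2-oxoglutarate-dependent demethylases, 2-oxoglutarate metabolism, proteasome and histones. Some genes sit in more than 1 list. Lists were tested with fry from limma, with Benjamini-Hochberg adjustment over the lists of a comparison. Fry tests whether the members move, on balance, one way, and does not compare them with other genes; camera with a preset correlation of 0.01 and with an estimated correlation, which does compare, was an alternative. Of the list calls, only that of mast cell genes in the difference between the days held with an estimated correlation.

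Named genes were Idh1, Idh2, Dnmt3a, Nras, Kit and Itgam in every comparison; per comparison up to 8 highest and 8 lowest fold changes among genes that passed, had a mean log2 CPM of at least 3 and did not overlap between the libraries compared, without unnamed gene models and antigen receptor segments; up to 3 members per list and direction with the largest change among those that passed, or 2 of highest expression where none did; and up to 6 genes of smallest adjusted p for the difference between the days. Examples were taken from these. Genes for which a group had 0 counts in every library are not given with fold changes in the comparison concerned, apart from Ccl4, whose counts are stated beside it.

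The steps were tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold. For day 5, 60% and 83% of these were called and 9 of the unchanged genes were (11558 genes in the step); for day 14, 25%, 80% and 1 (11563 genes); for relapse minus vehicle, 62%, 90% and 12 (11664 genes). All called changed genes had the right direction. Changes of 2-fold were thus missed more often at day 14. The simulated libraries had the same spread per gene in every group, whereas the real relapse libraries differed more among themselves. Recovery for relapse minus vehicle may therefore be overstated. Pairs of libraries of a group were compared by a chi-square test over genes with at least 20 counts, with 1.87 to 17.6 per gene, so none of these pairs were duplicates.

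The alternatives fixed in advance were DESeq2 size factors, no filter, a filter of 10 counts in 2 libraries, DESeq2, limma-voom, only the groups compared in the fit, the replicate number as a block, each replicate left out in turn, and single-day control groups. Upper-quartile scaling, scaling by the total without ribosomal RNA, removal of the ribosomal RNA models and thinning of every library to 1259982 counts were added after the data were seen. With scaling by the total without ribosomal RNA the median log2 fold change of all genes was −0.103 at day 14 and in the mean effect, against −0.0062 and −0.0094 with TMM. Under each scaling the share of higher calls moved by less than 10 percentage points.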

Results

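Gene expression was measured in leukemic progenitor cells of mice that had been transplanted with I1DN cells, the name the labels give to a mouse leukemia with mutant IDH1. AG120 (AG-120, also known as ivosidenib) is an inhibitor of mutant IDH1, the enzyme form that makes the metabolite 2-hydroxyglutarate. Cells positive for cKit and negative for CD11b were sorted from each mouse, and their RNA was sequenced from the 3′ end of transcripts with the QuantSeq kit. The 14 libraries fell into 5 groups: AG120 for 5 days (n = 3), vehicle for 5 days (n = 3), AG120 for 14 days (n = 2), vehicle for 14 days (n = 2), and disease that had relapsed after 28 days of AG120 (n = 4). Total counts per library ran from 4995738 in AG120 day 14 replicate 1 to 8691708 in relapse replicate 4. Ribosomal RNA gene models took 50.9% to 74.8% of each library, which left 1259982 to 3358874 counts for all other genes. The share of ribosomal RNA was 63.7% ± 1.43 (SD, n = 3) in AG120 day 5 and 55.9% ± 4.59 (SD, n = 3) in vehicle day 5. It was 68.9% ± 8.27 (SD, n = 2) in AG120 day 14, 62.0% ± 8.73 (SD, n = 2) in vehicle day 14 and 63.6% ± 2.27 (SD, n = 4) in relapse. Mitochondrially encoded genes took at least 0.871% of the other counts in each AG120 library, 0.626% to 0.801% in vehicle and 0.719% to 0.766% in relapse.

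The first principal component of log2 CPM held 71.4% of the variance and separated the AG120 libraries, at −79.5 to −49.7, from vehicle, at 28.4 to 32.5, and from relapse, at 31.2 to 43.8. The 4 relapse libraries were spread along the second component (8.12%), at −33.0, 24.6, 20.9 and −30.0 for replicates 1 to 4. Replicates 1 and 4 lay close together, as did replicates 2 and 3. Their log2 CPM correlated at 0.972 and 0.957, against 0.920 to 0.935 for the other relapse pairs. Pearson correlations of log2 CPM between replicates were 0.920 to 0.972 in relapse, 0.978 to 0.981 in AG120 day 5, 0.980 to 0.987 in vehicle day 5, 0.967 in AG120 day 14 and 0.981 in vehicle day 14. No pair of libraries of the same group matched within sampling noise, so each was counted as 1 replicate.

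The first question was what 5 days of AG120 changed in the sorted progenitors. Cd34, which encodes a surface sialomucin of stem and progenitor cells, fell 13.7-fold, from 139 ± 11.2 CPM (SD, n = 3) in vehicle to 10.1 ± 2.13 CPM (SD, n = 3) in AG120. Red cell genes moved the other way: Ermap, an erythroid membrane protein, rose 45.7-fold, from 3.99 ± 1.40 to 185 ± 13.1 CPM (SD, n = 3 each). Car1, the carbonic anhydrase of red cells, rose by 4.83 ± 0.36 log2 units (SE, adjusted p = 1.83e-07). The glycosyltransferase gene Gcnt2 fell by 5.07 ± 0.26 log2 units (SE, adjusted p = 1.31e-09), and the lymphotoxin gene Ltb fell by 4.32 ± 0.28 (SE, adjusted p = 1.67e-08). Among 11994 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2410 rose and 2320 fell, and 849 and 1458 of these changed more than 2-fold. Cd34 lies on chromosome 1 from 194938819 to 194961279 and Ermap on chromosome 4 from 119175457 to 119190011 (GRCm38).

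Of 26 measured erythroid genes, 19 rose at day 5 and 7 did not pass, with a median log2 fold change of 3.10. Examples were Rhd, a blood group antigen, at 4.58 ± 0.62 and Blvrb, a biliverdin reductase of red cells, at 4.09 ± 0.57 (log2, SE). The list rose by fry (adjusted p = 0.0027, adjusted p = 0.474 with an estimated correlation), and 19 members passed when adjusted over the list alone. Of 25 stem and leukemia stem cell genes, 15 fell, 3 rose and 7 did not pass (18 adjusted over the list alone), with a median of −1.98. Cd34 was at −3.78 ± 0.17, whereas Eng, endoglin, a co-receptor for TGF-beta, rose by 1.13 ± 0.23. The stem cell list fell by fry (adjusted p = 0.000384, adjusted p = 0.425 with an estimated correlation).

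Genes of the granulocyte and monocyte lineages were lower at day 5. Of 20 primary granule and promyelocyte genes 11 fell and 2 rose (15 adjusted over the list alone, median −1.55), among them Serpinb1a, a granule protease inhibitor, at −2.64 ± 0.18, and Csf3r, the G-CSF receptor, at −2.98 ± 0.23. Mt1, a metallothionein held by the same list, rose by 2.99 ± 0.48. Of 26 secondary granule and neutrophil genes 10 fell and 1 rose (12 adjusted over the list alone, median −2.14), with Lyz2, lysozyme, at −3.62 ± 0.38 and the chemokine receptor gene Cxcr2 at −3.38 ± 0.40. Of 23 monocyte and macrophage genes 7 fell and 2 rose (9 adjusted over the list alone, median −0.81), with Irf8, a regulator of monocyte fate, at −3.77 ± 0.68 and Cd68 at −3.11 ± 0.32. The 3 lists fell by fry with adjusted p of 0.00297, 0.000384 and 0.00297, in that order. Their calls did not hold with an estimated correlation, at adjusted p = 0.474 with an estimated correlation for the first and last lists and adjusted p = 0.425 with an estimated correlation for the neutrophil list.

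Lists of markers of other lineages were lower too, each by fry. Most members of the T and NK cell, stromal and B cell lists were not among the genes tested. Their fall does not show that such cells were present and then lost. Of 17 megakaryocyte and platelet genes 9 fell (9 adjusted over the list alone, median −1.98), with Plek, a platelet protein kinase C substrate, at −3.26 ± 0.50. Of 13 mast cell, basophil and eosinophil genes 7 fell and 2 rose (10 adjusted over the list alone, median −1.23), with Il5ra, the interleukin-5 receptor, at −2.77 ± 0.48 and Il1rl1, the interleukin-33 receptor, at 2.83 ± 0.28. Of 8 T and NK cell genes 3 fell (3 adjusted over the list alone, median −0.83), with Nkg7, which is also in the primary granule list, at −1.88 ± 0.15. Of 6 stromal and endothelial genes 4 fell (4 adjusted over the list alone, median −1.35), with the adhesion molecule gene Pecam1 at −2.23 ± 0.24 and Vim, vimentin, at −1.70 ± 0.17. Of 3 B and plasma cell genes 2 fell (2 adjusted over the list alone, median −1.11). The fry adjusted p values were 0.0027, 0.00213, 0.000251, 1.39e-06 and 0.000848 in this order. No call held with an estimated correlation, at adjusted p = 0.474 with an estimated correlation for the megakaryocyte, mast cell and B cell lists, adjusted p = 0.447 with an estimated correlation for T and NK cells and adjusted p = 0.26 with an estimated correlation for stromal genes.

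The lists of MYC targets, the ATF4 response and 2-oxoglutarate metabolism rose at day 5 by fry. Of 40 MYC target and ribosome biogenesis genes 37 rose, none fell and 3 did not pass (39 adjusted over the list alone, median 0.97). They included Rrp9, a component of the small nucleolar ribonucleoprotein, at 1.71 ± 0.17, Odc1, ornithine decarboxylase, at 1.61 ± 0.21, and the mitochondrial chaperone gene Hspd1 at 1.49 ± 0.23. The list rose by fry (adjusted p = 0.000859, adjusted p = 0.472 with an estimated correlation). Of 28 ATF4 and integrated stress response genes 14 rose and none fell (14 adjusted over the list alone, median 0.62, fry adjusted p = 0.0046, adjusted p = 0.492 with an estimated correlation). Of 26 genes of 2-oxoglutarate, glutamate and NADPH metabolism 10 rose and 3 fell (13 adjusted over the list alone, median 0.34, fry adjusted p = 0.0039, adjusted p = 0.474 with an estimated correlation). Gclm, the regulatory subunit of glutathione synthesis, rose by 2.12 ± 0.14 and Nqo1, a quinone reductase, by 1.49 ± 0.27, whereas Glud1, glutamate dehydrogenase, fell by 0.73 ± 0.13.

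Inflammatory, survival and lysosomal lists fell at day 5. Of 23 TNF and NF-kB genes 8 fell and 2 rose (10 adjusted over the list alone, median −0.49), with the adhesion molecule gene Icam1 at −2.86 ± 0.39. Fry called this shift (adjusted p = 0.00994, but adjusted p = 0.545 with an estimated correlation). Of 12 TGF-beta response genes 3 fell (3 adjusted over the list alone, median −0.47), with the receptor gene Tgfbr2 at −1.64 ± 0.39. The list shifted by fry (adjusted p = 0.00406, but adjusted p = 0.51 with an estimated correlation). Of 23 p53 target and apoptosis genes 8 fell and 5 rose (13 adjusted over the list alone, median −0.28, fry adjusted p = 0.0039, adjusted p = 0.539 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.63 ± 0.23, while Phlda3, a p53-induced inhibitor of AKT, rose by 3.04 ± 0.44. Of 30 lysosome and autophagy genes 10 fell and 2 rose (12 adjusted over the list alone, median −0.37), with Grn, progranulin, at −1.96 ± 0.17. By fry, this list was called (adjusted p = 0.000251, but adjusted p = 0.425 with an estimated correlation). Of 33 cholesterol and lipid synthesis genes 8 fell and none rose (7 adjusted over the list alone, median −0.13), with Srebf2, the regulator of sterol synthesis, at −0.90 ± 0.19. This shift passed by fry (adjusted p = 0.00297, but adjusted p = 0.51 with an estimated correlation). At day 5, 39.4% of all tested genes were called, a larger share than in the TGF-beta, cholesterol, monocyte and macrophage, and T and NK cell lists.

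**Figure D1:**
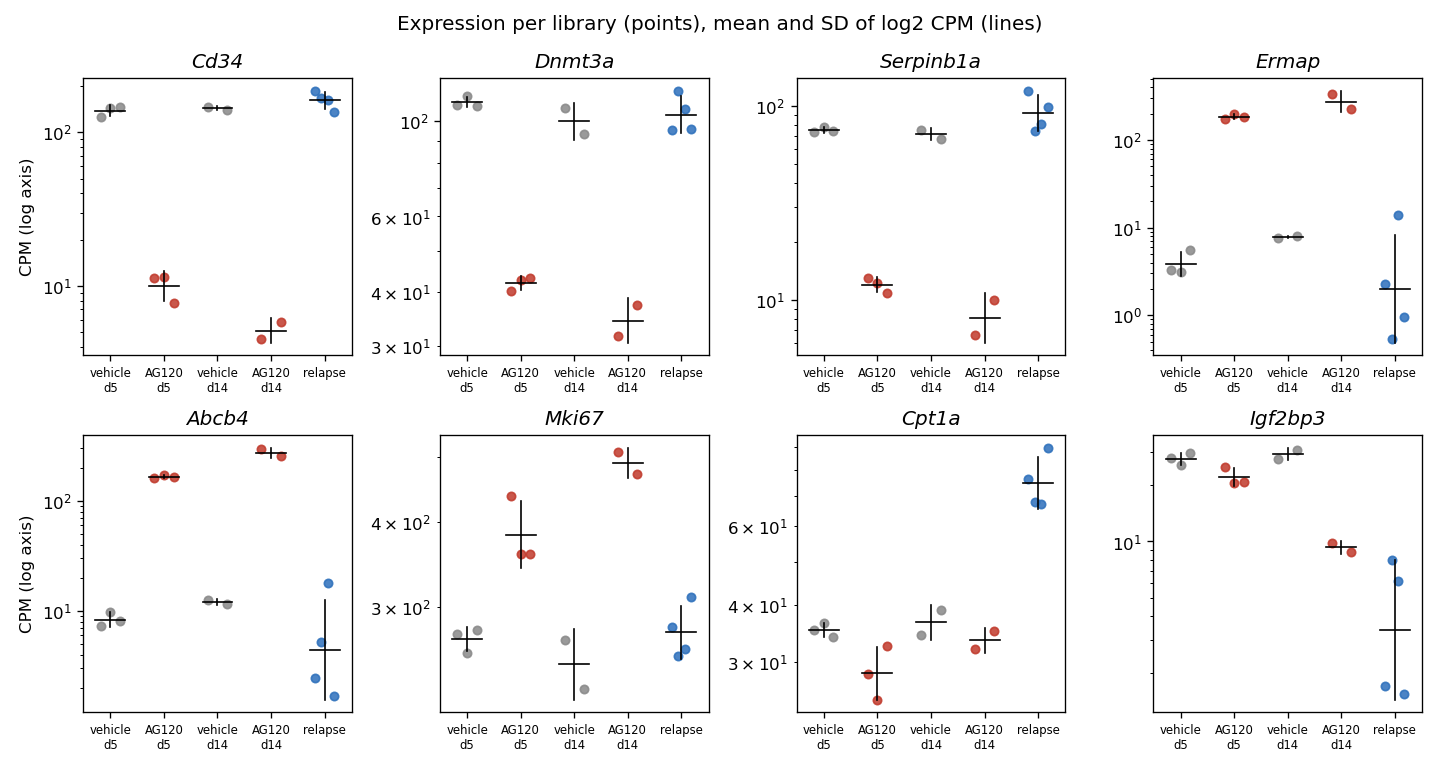
Expression of 8 genes in each library (points), as CPM on a logarithmic axis, by group (vehicle grey, AG120 red, relapse blue), with the mean (horizontal line) and SD (vertical line) of log2 CPM per group. Cd34, Dnmt3a and Serpinb1a were lower in the 5 AG120 libraries than in all others and Ermap and Abcb4 were higher, while Cpt1a and Igf2bp3 differed between relapse and vehicle.

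The genes fixed for the model and the sort did not move alike at day 5. Dnmt3a, a DNA methyltransferase, fell by 1.39 ± 0.12 log2 units (SE, adjusted p = 1.55e-07), Idh2, the mitochondrial isocitrate dehydrogenase, fell by 0.85 ± 0.15 (adjusted p = 0.000229), and Itgam, which encodes CD11b, fell by 2.02 ± 0.53 (adjusted p = 0.0103). Idh1 was at −0.71 ± 0.30 (adjusted p = 0.0789), Kit at −0.41 ± 0.35 (adjusted p = 0.393) and Nras at −0.06 ± 0.13 (adjusted p = 0.741), none of which passed. Counts per gene did not separate mutant from normal alleles.

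The comparison at day 14 asked what longer treatment changed, with 2 libraries against 2. AG120 day 14 replicate 1 had 74.8% ribosomal RNA, 1259982 other counts and 15336 genes detected, against 63.1%, 1978091 and 17243 in replicate 2. Cd34 fell 27.3-fold, from 144 ± 4.20 to 5.14 ± 0.94 CPM (SD, n = 2 each), and Tmem176b, a membrane protein of myeloid cells, fell by 5.68 ± 0.38 log2 units (SE, adjusted p = 1.87e-08). The transcription factor gene Sox4 fell by 5.09 ± 0.76 (adjusted p = 0.000562) and Erg, a regulator of blood stem cells, by 5.45 ± 0.70 (adjusted p = 3e-05). Ermap rose by 5.16 ± 0.90 (adjusted p = 0.00161), Cpox, an enzyme of heme synthesis, by 3.70 ± 0.29 (adjusted p = 2.28e-07), and Sptb, erythroid beta-spectrin, by 5.97 ± 0.96 (adjusted p = 0.00057). By edgeR, 2010 genes rose and 2149 fell, 4159 in all, and without vehicle day 14 replicate 2 the total was 2752. Idh1 fell by 1.95 ± 0.41 (adjusted p = 0.00255), Idh2 by 1.69 ± 0.19 (adjusted p = 3.44e-06) and Dnmt3a by 1.53 ± 0.15 (adjusted p = 8.44e-07). Kit, at −1.63 ± 0.49 (adjusted p = 0.022), lost its call without AG120 day 14 replicate 1 (adjusted p = 0.0943) or 2 (0.115) and without vehicle day 14 replicate 1 (0.0589) or 2 (0.0747), and with no filter on low counts (0.0541). Itgam was at −1.19 ± 0.61 (adjusted p = 0.154) and Nras at −0.20 ± 0.16 (adjusted p = 0.358).

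At day 14, 22 of 26 erythroid genes rose and none fell (25 adjusted over the list alone, median 4.31), and the list rose by fry (adjusted p = 0.00172, adjusted p = 0.308 with an estimated correlation). Of 25 stem cell genes 13 fell and 3 rose (17 adjusted over the list alone, median −2.20), with the ETS factor gene Fli1 at −2.75 ± 0.25 and Mllt3, a stem cell maintenance factor, at 3.85 ± 0.79. As a list they shifted by fry (adjusted p = 0.000426, but adjusted p = 0.269 with an estimated correlation). Of 20 primary granule genes 12 fell and 1 rose (15 adjusted over the list alone, median −2.45), with Ms4a3, a marker of granulocyte-monocyte progenitors, at −4.08 ± 0.46 and Plac8 at −3.50 ± 0.40. Fry called this shift (adjusted p = 0.000746, but adjusted p = 0.292 with an estimated correlation). Of 23 TNF and NF-kB genes 17 fell and 1 rose (19 adjusted over the list alone, median −2.89, fry adjusted p = 0.000166, adjusted p = 0.269 with an estimated correlation). The riser was Tnfaip2 at 2.33 ± 0.23. Of 13 mast cell, basophil and eosinophil genes 9 fell and 1 rose (11 adjusted over the list alone, median −2.87), with the sialic acid receptor gene Siglecf at −4.52 ± 0.79. The list shifted by fry (adjusted p = 1.04e-05, but adjusted p = 0.094 with an estimated correlation).

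Secondary granule and neutrophil genes had a median of 0.06 at day 14 with fry pointing down (adjusted p = 0.0924), and 1 of 26 rose and 5 fell (6 adjusted over the list alone). Monocyte genes had a median of 0.12 with fry pointing down (adjusted p = 0.822), with 4 of 23 higher and 4 lower (8 adjusted over the list alone). At day 14, 34.7% of all tested genes were called, a larger share than in the neutrophil and dendritic cell lists. Dendritic cell and MHC class II genes had a median of 0.66, with 1 of 9 higher and 1 lower (2 adjusted over the list alone), and were called up by fry (adjusted p = 0.0346, adjusted p = 0.574 with an estimated correlation). Their call was lost without AG120 day 14 replicate 1 (adjusted p = 0.234) or vehicle day 14 replicate 1 (0.13) or 2 (0.127). Of 40 MYC target genes 28 rose and none fell (31 adjusted over the list alone, median 0.83, fry adjusted p = 0.00894, adjusted p = 0.515 with an estimated correlation). The MYC list lost its call without vehicle day 14 replicate 1 (adjusted p = 0.0553).

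To ask where the effect of AG120 differed between the days, the day 5 effect was subtracted from the day 14 effect. Muc13, a transmembrane mucin, differed most by adjusted p, at −3.13 ± 0.29 log2 units (SE, adjusted p = 6.01e-05). It was at 0.14 ± 0.16 at day 5 (adjusted p = 0.517) and fell by 2.99 ± 0.24 at day 14, to 7.28 ± 0.68 CPM against 57.7 ± 7.0 CPM in vehicle (SD, n = 2 each). Cd63, a tetraspanin of granules and lysosomes, fell further at day 14, with a difference of −1.35 ± 0.18 (adjusted p = 0.00286), as did Cbfb, a partner of RUNX proteins, at −1.64 ± 0.22 (adjusted p = 0.00302), and the phosphatase gene Ptpn18 at −1.53 ± 0.20 (adjusted p = 0.00286). St3gal2, a sialyltransferase, fell by 1.96 ± 0.16 at day 5 and was at −0.18 ± 0.19 at day 14, a difference of 1.79 ± 0.25 (adjusted p = 0.00445). Muc13 lies on chromosome 16 from 33794037 to 33819934.

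In this difference, 25 genes were higher and 87 lower by edgeR, 112 in all (22.3% of them higher). The total was 869 (41.0% higher) with only the groups compared in the fit, 374 (21.7% higher) with no filter on low counts, 187 (31.6%) with DESeq2, 53 (30.2%) with thinned libraries and 31 (35.5%) with limma-voom. It also rested on single libraries, at 13 without AG120 day 14 replicate 1 and 15 without replicate 2, 17 and 21 without vehicle day 14 replicate 1 or 2, 35, 50 and 47 without AG120 day 5 replicates 1 to 3, and 61, 42 and 34 without vehicle day 5 replicates 1 to 3. Gmfg, a regulator of actin branching, was at −1.95 ± 0.28 (adjusted p = 0.00445) and lost its call without AG120 day 14 replicate 2 (adjusted p = 0.064) and with limma-voom (0.0583). The fixed genes did not pass, with Idh1 at −1.24 (adjusted p = 0.339), Idh2 at −0.84 (0.122), Kit at −1.22 (0.44), Itgam at 0.83 (0.769), Dnmt3a at −0.13 (0.851) and Nras at −0.14 (0.858).

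Mast cell, basophil and eosinophil genes were shifted further down at day 14 as a list (median difference −1.51, fry adjusted p = 0.00106, adjusted p = 0.0182 with an estimated correlation), although none of 13 passed alone and 2 passed when adjusted over the list alone. Stromal genes were also shifted down (median −0.96), with none of 6 passing and 3 adjusted over the list alone. By fry, this list was called (adjusted p = 0.00106, but adjusted p = 0.069 with an estimated correlation). TNF and NF-kB genes had a median difference of −1.55, with 2 of 23 lower (10 adjusted over the list alone, fry adjusted p = 0.00942, adjusted p = 0.069 with an estimated correlation). MAPK and RAS feedback genes had a median of −0.70, with 2 of 21 lower (2 adjusted over the list alone, fry adjusted p = 0.0123, adjusted p = 0.069 with an estimated correlation). Both lost their call without AG120 day 14 replicate 2, at adjusted p = 0.0586 and 0.0665. Immediate early and dissociation-stress genes, which respond to handling of cells, had a median difference of −1.42 (fry adjusted p = 0.23), with none of 19 passing, also over the list alone. Their mean log2 CPM was 3.23 and 3.80 in AG120 day 14, 4.85 and 4.84 in vehicle day 14, 4.56 to 5.60 in AG120 day 5 and 3.97 to 5.46 in vehicle day 5. Erythroid genes had a median difference of 1.16 (fry adjusted p = 0.502), and none passed, also when adjusted over the list alone, where the count was 0.

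The mean of the effects at both days, with 5 libraries against 5, gave 3065 genes higher and 3083 lower by edgeR, 51.3% of those tested. Cd34 fell by 4.27 ± 0.14 log2 units (SE, adjusted p = 5.85e-12) and Tespa1 by 4.55 ± 0.20 (adjusted p = 3.54e-11). Ermap rose by 5.33 ± 0.61 (adjusted p = 4.42e-05), Car1 by 4.97 ± 0.29 (adjusted p = 3.8e-09), the phospholipid transporter gene Abcb4 by 4.40 ± 0.48 (adjusted p = 3.02e-05) and the metallothionein gene Mt2 by 5.16 ± 0.55 (adjusted p = 2.66e-05). Idh1 fell by 1.33 ± 0.25 (adjusted p = 0.000708), Idh2 by 1.27 ± 0.12 (adjusted p = 1.8e-07), Dnmt3a by 1.46 ± 0.10 (adjusted p = 2.49e-09) and Itgam by 1.6 ± 0.40 (adjusted p = 0.00575), while Nras was at −0.13 ± 0.10 (adjusted p = 0.305). Kit, at −1.02 ± 0.30 (adjusted p = 0.0139), lost its call without AG120 day 14 replicate 2 (adjusted p = 0.0577).

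Cell cycle genes were higher in the mean of both days. Of 47 G1/S and DNA replication genes 27 rose and 4 fell (32 adjusted over the list alone, median 0.36), with Ccne1, cyclin E1, at 1.82 ± 0.19 and Cdc6, a replication licensing factor, at 1.23 ± 0.14. This shift passed by fry (adjusted p = 0.00202, but adjusted p = 0.543 with an estimated correlation). Of 48 G2/M and mitosis genes 28 rose and 1 fell (29 adjusted over the list alone, median 0.40), with Hmmr at 1.02 ± 0.12 and the cytokinesis gene Anln at 0.94 ± 0.14. As a list they shifted by fry (adjusted p = 0.00434, but adjusted p = 0.584 with an estimated correlation). The G1/S call at day 5 was lost without any 1 of the 6 libraries (adjusted p = 0.0539 to 0.0888) and with the replicate number as a block (0.0665), and at day 14 without AG120 replicate 2 (0.0509) or vehicle replicate 1 (0.0553). The G2/M call at day 5 was lost without AG120 replicate 1 (0.0781) or 2 (0.0511) or vehicle replicate 1 (0.077) or 2 (0.07), and at day 14 without any 1 of the 4 libraries (0.0861 to 0.115). Pimreg, a mitotic regulator, was the G2/M member that fell in the mean effect, at −2.55 ± 0.24. Of 19 cell cycle inhibitor and quiescence genes 6 fell and 3 rose (9 adjusted over the list alone, median −0.48), with Cdkn1a at −2.07 ± 0.20 and Cdkn2d at −1.79 ± 0.15. Fry called this shift (adjusted p = 0.00653, but adjusted p = 0.609 with an estimated correlation). Mki67, a proliferation marker chosen after its values were seen, was at 385 ± 45.1 CPM in AG120 and 269 ± 10.9 CPM in vehicle at day 5 (SD, n = 3 each), and at 490.1 ± 25 and 247 ± 29.7 CPM at day 14 (SD, n = 2 each). Mitosis and replication genes rose in the same libraries in which erythroid genes rose, of which 22 of 26 rose over both days (median 3.61).

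Of 26 proteasome genes 15 rose and none fell over both days (16 adjusted over the list alone, median 0.45), with Psmc2 at 0.95 ± 0.14. The list shifted by fry (adjusted p = 0.00653, but adjusted p = 0.604 with an estimated correlation). Of 45 oxidative phosphorylation and TCA cycle genes 24 rose and 3 fell (27 adjusted over the list alone, median 0.38), with the complex I gene Ndufs1 at 0.92 ± 0.12. By fry, this list was called (adjusted p = 0.0172, but adjusted p = 0.609 with an estimated correlation). That call was lost without AG120 day 14 replicate 2 (adjusted p = 0.0895) or vehicle day 14 replicate 1 (0.0688). Of 25 genes for 2-oxoglutarate-dependent chromatin and DNA demethylases and DNA methyltransferases 7 fell and 2 rose (9 adjusted over the list alone, median −0.26), with Dnmt3b at −1.31 ± 0.22 and the dioxygenase gene Tet2 at −0.85 ± 0.14. This shift passed by fry (adjusted p = 0.0103, but adjusted p = 0.625 with an estimated correlation). The share of its members called was below the 51.3% of all tested genes called in the mean effect. Of 17 histone genes 8 fell and 4 rose (12 adjusted over the list alone, median −0.28), with H2afy, the macroH2A variant, at −1.41 ± 0.13. As a list they shifted by fry (adjusted p = 0.00394, but adjusted p = 0.609 with an estimated correlation). Of 21 MAPK and RAS feedback genes 8 fell and 2 rose (10 adjusted over the list alone, median −0.86), with Dusp5, an ERK phosphatase, at −2.97 ± 0.35. Fry called this shift (adjusted p = 0.00018, but adjusted p = 0.369 with an estimated correlation).

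Of 35 hypoxia and glycolysis genes 11 fell and 9 rose over both days (20 adjusted over the list alone, median −0.35), with Pkm, pyruvate kinase, at −2.67 ± 0.17 and Hk1, hexokinase, at 1.04 ± 0.09. The list shifted by fry (adjusted p = 0.00653, but adjusted p = 0.609 with an estimated correlation). The call was lost without AG120 day 14 replicate 1 (adjusted p = 0.0602). Of 38 interferon response genes 12 fell and 5 rose (17 adjusted over the list alone, median −0.20), with Ifi203 at −3.53 ± 0.16 and Isg15 at 1.29 ± 0.22. By fry, this list was called (adjusted p = 0.0172, but adjusted p = 0.625 with an estimated correlation). The interferon call was lost without AG120 day 14 replicate 1 (0.0838) or vehicle day 14 replicate 1 (0.055). The shares of interferon, MAPK and RAS feedback, and cell cycle inhibitor genes called were also below the 51.3% of all tested genes. Among the lists not called by fry were cytosolic ribosomal proteins (6 of 51 higher and 2 lower, 4 adjusted over the list alone, median 0.05, adjusted p = 0.637), dendritic cell and MHC class II genes (1 of 9 higher and 1 lower, 2 adjusted over the list alone, median 0.05, adjusted p = 0.0906), immediate early and dissociation-stress genes (2 of 19 higher and 3 lower, 4 adjusted over the list alone, median −0.35, adjusted p = 0.487) and unfolded protein response genes (1 of 23 higher and 8 lower, 8 adjusted over the list alone, median −0.34, adjusted p = 0.0977).

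Genes called at both days nearly all moved the same way. Of the genes tested, 1471 rose at both days and 1559 fell at both, where independent lists of these sizes would share 404 and 416, and 17 were called in opposite directions. Across the 11994 genes the log2 fold changes of the 2 days, which share no library, correlated at Pearson 0.774 and Spearman 0.763. Simulated unchanged groups gave a Pearson value of 0.009. They held no effect and the 2 comparisons shared no library, so their low value was fixed by construction. Genes are not independent replicates, so no p is given.

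**Figure D2:**
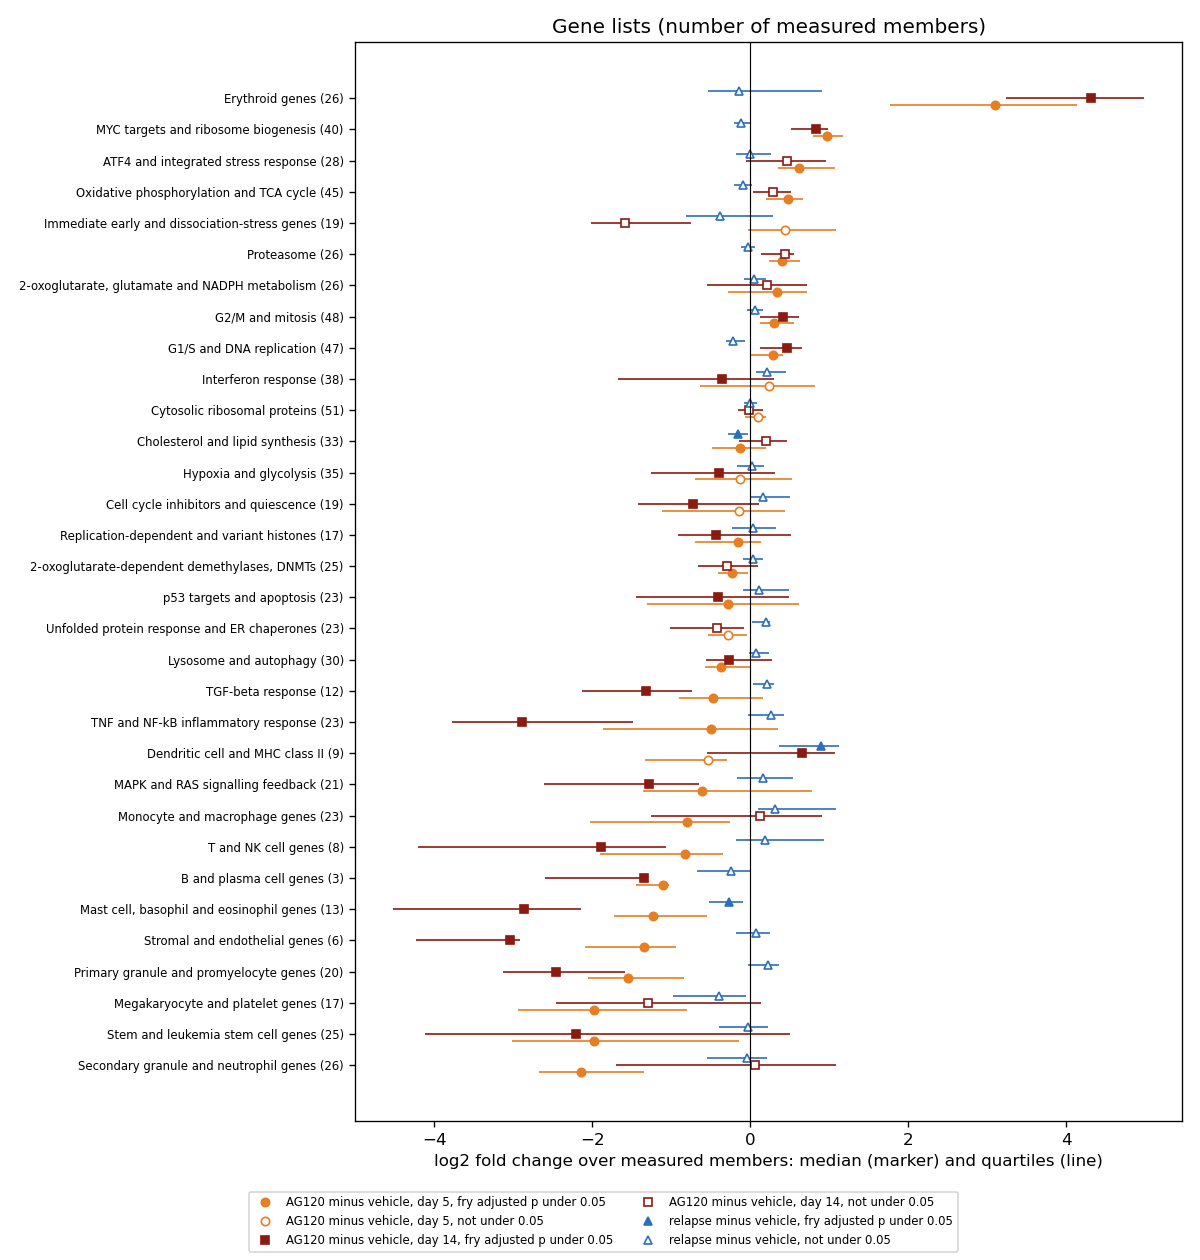
Median (marker) and quartiles (line) of the log2 fold change over the measured members of each of 32 gene lists, for AG120 minus vehicle at day 5 (orange circles) and day 14 (dark red squares) and for relapse minus vehicle (blue triangles), filled where the fry adjusted p was under 0.05. Erythroid genes lie at 3.10 and 4.31 under AG120 and at −0.14 in relapse.

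Relapse was compared with vehicle to ask what differed once the disease had returned, with 4 libraries against 5. Cpt1a, which admits fatty acids to mitochondria for oxidation, was higher in relapse by 1.06 ± 0.11 log2 units (SE, adjusted p = 0.000142), at 75.1 ± 10.4 CPM (SD, n = 4) against 35.2 ± 1.30 (SD, n = 3) and 36.7 ± 3.22 (SD, n = 2) in vehicle at days 5 and 14. Igf2bp3, an RNA-binding protein of fetal cells and tumors, was lower by 2.71 ± 0.34 log2 units (adjusted p = 0.00492), at 4.37 ± 3.25 CPM (SD, n = 4) against 27.5 ± 1.98 and 29.1 ± 2.22 CPM. It missed the threshold when only the groups compared entered the fit (adjusted p = 0.0755). Rnu11, a small nuclear RNA of the minor spliceosome, was lower by 1.75 ± 0.17 (adjusted p = 5.44e-05), which is uncertain because its gene model overlaps another. Cpt1a lies on chromosome 19 from 3322334 to 3385733 and Igf2bp3 on chromosome 6 from 49085223 to 49214957.

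By edgeR, 12 genes were higher and 10 lower in relapse than in vehicle. An unadjusted p under 0.05 by edgeR was held by 1389 of 11994 genes, more than chance alone would give on average. The total of 22 rested on single libraries: it was 8 without vehicle day 14 replicate 1 or 2, 14, 10 and 9 without vehicle day 5 replicates 1 to 3, and 48, 117 and 106 without relapse replicates 1 to 3. It was 267 with no filter on low counts, 120 with DESeq2, 7 with only the groups compared and 6 with vehicle day 14 alone as control. Among the 22, Cdkn2a, which encodes the inhibitors p16 and p19, was higher by 4.23 ± 0.65 (adjusted p = 0.0245) and Cdkn1a by 0.88 ± 0.16 (adjusted p = 0.033). Cdkn2a lost its call without vehicle day 14 replicate 1 (adjusted p = 0.136) or 2 (0.242) and without vehicle day 5 replicates 1 to 3 (0.0512, 0.0842 and 0.0701), with limma-voom (0.205), with only the groups compared (0.154) and with vehicle day 14 alone as control (0.286). Cdkn1a lost its call without relapse replicate 4 (0.0737), without vehicle day 14 replicate 1 (0.193) or 2 (0.074), and without vehicle day 5 replicates 1 to 3 (0.0615, 0.0933 and 0.0651). The Cdkn1a call was also lost with only the groups compared (0.135), with the replicate number as a block (0.155) and with vehicle day 14 alone as control (0.34). The mitochondrial ribosome factor gene Malsu1 was lower by 0.84 ± 0.12 (adjusted p = 0.00499), and it missed the threshold with only the groups compared (0.0572) or with vehicle day 14 alone as control (0.0651). The 3′ ends of Malsu1 and Igf2bp3 overlap on opposite strands, so reads of the 2 may not be told apart. No vehicle group of the relapse time was analysed here, so time and relapse could not be separated.

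None of the fixed genes passed between relapse and vehicle: Idh1 was at 0.08 (adjusted p = 0.938), Idh2 at −0.07 (0.852), Dnmt3a at −0.02 (0.962), Nras at −0.02 (0.972), Kit at −0.03 (0.983) and Itgam at 1.04 ± 0.35 (0.275). Of the lists called in the mean effect of AG120, erythroid genes had a median of −0.14 (fry adjusted p = 0.753), stem cell genes −0.03 (0.789), MYC targets −0.12 (0.677) and G2/M genes 0.06 (0.759), with none of their members passing. Idh1 and the stem cell genes Sox4, Meis1 and Itga2b differed among the relapse libraries, as given below per library. A relapse mean near that of vehicle therefore does not show that each relapse library resembled vehicle. The mean log2 CPM of erythroid genes was 0.59, 1.45, 3.41 and 0.22 in relapse replicates 1 to 4 and 1.45 to 2.37 in the vehicle libraries. The 3 lists called by fry each depended on at least 1 library. Mast cell, basophil and eosinophil genes were shifted down (median −0.26, 0 of 13 passing and 2 adjusted over the list alone, fry adjusted p = 0.0104, adjusted p = 0.0758 with an estimated correlation), as were cholesterol genes (median −0.16, 1 of 33 lower and 3 adjusted over the list alone, fry adjusted p = 0.0104, adjusted p = 0.0758 with an estimated correlation). Both were lost without vehicle day 14 replicate 1, at adjusted p = 0.154 and 0.089. Dendritic cell and MHC class II genes were shifted up (median 0.89, 0 of 9 passing and 2 adjusted over the list alone, fry adjusted p = 0.0434, adjusted p = 0.0758 with an estimated correlation). Their call was lost without relapse replicate 1 (0.0527) or 3 (0.0522), vehicle day 14 replicate 1 (0.154) or 2 (0.21), or vehicle day 5 replicates 1 to 3 (0.0755, 0.0531 and 0.107), and with the replicate number as a block (0.0904).

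Relapse was also compared with AG120 on treatment, to ask whether expression under the drug persisted, with 4 libraries against 5. Cd34 was higher in relapse by 4.48 ± 0.15 log2 units (SE, adjusted p = 3.82e-12), at 163 ± 21.0 CPM (SD, n = 4). Erythroid genes were lower, with Klf1, the erythroid Krüppel-like factor, at −5.40 ± 0.40 (adjusted p = 1.8e-07), Ermap at −5.62 ± 0.66 (adjusted p = 5.55e-05) and Gata1, the regulator of red cell and platelet formation, at −3.90 ± 0.42 (adjusted p = 9.16e-06). By edgeR, 3352 genes were higher and 3129 lower in relapse, 54.0% of those tested. Dnmt3a was higher by 1.44 ± 0.10 (adjusted p = 4.09e-09), Idh1 by 1.40 ± 0.26 (adjusted p = 0.000567), Idh2 by 1.20 ± 0.12 (adjusted p = 5.45e-07) and Itgam by 2.64 ± 0.40 (adjusted p = 0.000177), and Nras was at 0.11 ± 0.11 (adjusted p = 0.391).

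Between relapse and AG120, 19 of 26 erythroid genes were lower and none higher (20 adjusted over the list alone, median −3.58, fry adjusted p = 1.45e-05, adjusted p = 0.331 with an estimated correlation). Of 40 MYC target genes 38 were lower (38 adjusted over the list alone, median −0.98), with Rrp9 at −1.71 ± 0.15. This shift passed by fry (adjusted p = 7.49e-05, but adjusted p = 0.331 with an estimated correlation). Of 47 G1/S genes 34 were lower and 1 higher (35 adjusted over the list alone, median −0.57), with Ccne1 at −2.14 ± 0.22. As a list they shifted by fry (adjusted p = 7.49e-05, but adjusted p = 0.331 with an estimated correlation). Of 25 stem cell genes 17 were higher and 5 lower (23 adjusted over the list alone, median 2.1, fry adjusted p = 7.49e-05, adjusted p = 0.331 with an estimated correlation). Of 20 primary granule genes 16 were higher and 1 lower (18 adjusted over the list alone, median 2.37), with Serpinb1a at 3.21 ± 0.15. Fry called this shift (adjusted p = 0.000324, but adjusted p = 0.331 with an estimated correlation). Of 23 TNF and NF-kB genes 17 were higher and 2 lower (20 adjusted over the list alone, median 2.30), with Icam1 at 4.25 ± 0.41. The list shifted by fry (adjusted p = 5.29e-05, but adjusted p = 0.331 with an estimated correlation).

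Across genes, the mean effect of AG120 and relapse minus vehicle, which share the vehicle libraries, correlated at Pearson −0.110 and Spearman −0.156, where simulated unchanged groups gave a Pearson value of 0.434. The simulated groups held no AG120 effect, so their Pearson value is not a like measure for that of the data. The covariance, which is not divided by the spread of the effects, was −0.054 against 0.0435 simulated. With the vehicle groups split between the comparisons, Pearson values were −0.244 for the day 5 effect with vehicle day 14 as the control of relapse, and −0.0967 for the day 14 effect with vehicle day 5, where simulated unchanged groups gave −0.00695 and 0.00259. The Pearson values rested on single relapse libraries: without relapse replicate 2 the 3 were −0.0172, −0.131 and −0.0418, and without relapse replicate 3 they were −0.198, −0.307 and −0.173.

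Vehicle at day 14 was set against vehicle at day 5 as a background for time without drug, with 2 libraries against 3. Cd34 was at 144 ± 4.20 CPM (SD, n = 2) against 139 ± 11.2 CPM (SD, n = 3). No gene passed by edgeR, limma-voom or DESeq2 (0 by each). By edgeR, 574 of 11994 genes had an unadjusted p under 0.05, no more than chance alone would give on average. With only the groups compared in the edgeR fit 236 genes passed, and 33 with no filter on low counts. The fixed genes were at 0.25 for Idh1, 0.06 for Idh2, −0.15 for Dnmt3a, −0.10 for Nras, 0.01 for Kit and 0.35 for Itgam (log2). None of the 32 lists was called by fry, with medians of 0.44 for erythroid genes (adjusted p = 0.947), 0.60 for secondary granule and neutrophil genes (adjusted p = 0.506) and 0.42 for TNF and NF-kB genes (adjusted p = 0.25).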

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

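The tests of the 4 explanations below were chosen only after the result was seen, and the counts over other splits of the libraries before. Each value is given because a library lay far from the others of its group or because the effect of AG120 differed between the days by test.

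In the relapse group, 21 of 252 genes, lists and library measures tested had 1 library far from the other 3. For independent, normally distributed values, chance alone does this in about 1 in 20 groups. CPM values need not be normal, and genes such as the erythroid ones move together, so that rate is not a fair standard here. In relapse replicate 3, CPM was far above that of the other libraries for the erythroid genes Ermap (13.9 against 0.535 to 2.27), Klf1 (3.44 against 0.178 to 0.479), Car1 (3.03 against 0.378 to 0.535), Aqp1 (18.4 against 2.16 to 4.63) and Hbb-bt (156 against 21.2 to 33.7). The same replicate was far above the others in Cyth3 (7.29 against 2.16 to 3.02), Tnf (21.5 against 3.97 to 4.28), Ier5 (113 against 36.0 to 39.3), Btg2 (13.8 against 3.6 to 4.53), Gzmb (3.16 against 0.599 to 0.891) and Vwf (0.688 against 0.120 to 0.189), of which the last is 5 counts against 1 in each other library, too few to tell from counting error. Relapse replicate 1 was far above the others in Irf8 (30.6 CPM against 8.25 to 10.2), Hspa1a (13.6 against 0 to 0.599) and Tkt (365 against 299.9 to 307), and below them in Mxd1 (5.86 against 9.80 to 10.6). Relapse replicate 2 was far above the others in Dusp6 (120.27 CPM against 51.6 to 61.2) and Arap2 (46.1 against 28.8 to 29.7), and below them in Atf4 (75.4 against 148 to 156). Relapse replicate 4 was far above the others in Selp (35.4 CPM against 1.32 to 4.54) and H2-DMb1 (13.1 against 5.10 to 5.52), and below them in Perp (10.2 against 20.02 to 21.7).

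The effect of AG120 at day 14 minus that at day 5 passed the test of the difference for 20 named genes. Lower values were found for Muc13 (−3.13, log2), Pmaip1 (−3.76), Dusp5 (−3.71), Nfkbia (−3.20), BC100530 (−2.57), Gmfg (−1.95), Ikzf2 (−1.80), Myc (−1.74), Cbfb (−1.64), Ptpn18 (−1.53), Nkg7 (−1.52), Cd63 (−1.35), Psmb8 (−1.30) and Myb (−1.20). Ccl4 was at −8.18, but both AG120 day 14 libraries had 0 counts of it, so that size depends on the prior count. Higher values were found for Lyz2 (2.98), Itgb3 (2.32), St3gal2 (1.79), Kdm7a (1.78) and E2f2 (1.74). Muc13, Ptpn18, Cd63, Cbfb and St3gal2 kept their call without any 1 library. Without AG120 day 14 replicate 2 the call was lost for Pmaip1 (adjusted p = 0.111), Dusp5 (0.127), Nfkbia (0.149), BC100530 (0.191), Gmfg (0.064), Ikzf2 (0.202), Myc (0.149), Nkg7 (0.0968), Psmb8 (0.0688), Myb (0.064), Ccl4 (0.134), Lyz2 (0.126), Kdm7a (0.0857) and E2f2 (0.0688), and without AG120 day 14 replicate 1 for Itgb3 (0.0802). All of these but Gmfg were also lost without at least 1 other library. Of the lists, mast cell (−1.51), TNF and NF-kB (−1.55), stromal (−0.96), TGF-beta (−0.78) and MAPK (−0.70) genes were shifted down and cholesterol genes up (0.30). TGF-beta genes lost their call without AG120 day 14 replicate 1 (adjusted p = 0.0627) or 2 (0.0665) or vehicle day 14 replicate 1 (0.063), TNF and NF-kB (0.0586) and MAPK (0.0665) genes without AG120 day 14 replicate 2, and cholesterol genes without any 1 of the 4 day 14 libraries (0.0517 to 0.0627).

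Erythroid genes were higher in AG120 libraries, and granulocyte and monocyte lists were lower at day 5. At day 14 the primary granule list was still lower, but the neutrophil and monocyte lists were not called. RNA of mature red cells or free globin RNA would need the rise to be carried by globin and late red cell genes, but the 18 erythroid genes left without those had a median log2 change of 3.40 at day 5, a lower quartile of 2.25, and 17 passed. Cells added to unchanged leukemic cells that still gave 50% or more of the RNA could lower no gene more than 2-fold, whereas 6.02% of tested genes (722) had a 95% interval wholly below −1, and 6.73% (807) on a scale shifted by −0.0964. Near-complete replacement of the sorted cells by normal erythroid progenitors of the host stays open. Igf2bp3 was at 80.0% of its vehicle CPM at day 5 and at 32.0% at day 14, but its 3′ end overlaps that of Malsu1. Also at day 5, Kit, used for the sort, was at 75.6%. Cd34 was at 7.29%, Meis1 at 11.2%, Sox4 at 12.4% and Itga2b at 16.6%. Which of these genes normal progenitors lack is not known here, since no library of normal progenitors was analysed. A shift of the leukemic cells themselves toward an erythroid program may equally account for the pattern, and these counts do not separate the 2.

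Cell cycle and MYC target genes were higher in AG120 libraries, together with the erythroid genes. A change in the cell types within the gate, with erythroid progenitors that divide faster, might raise them without faster cycling of any one kind of cell. The G2/M list differed between the effects at day 14 and day 5 by a median of 0.049, which neither tracks nor opposes the erythroid list (median difference 1.16), whose own difference did not pass. The 2 explanations cannot be told apart from bulk libraries of these sorted cells.

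Other splits of the same libraries were fitted with the libraries compared alone. For the 2 relapse comparisons both days of the comparison group were also pooled into 1 group, so the counts differ from those of the other fits. For AG120 against vehicle at day 5 the real split gave 6186 genes and the highest other 0, and 10 splits are too few for a share under 0.05. For the mean of both days the real split gave 7147 genes, and 1 of 60 splits, the real one, gave as many. The highest other gave 869, in a split that reversed 1 day. For relapse minus AG120, the real split gave 4894 and the highest other of 100 drawn 2098, in a split of 4 AG120 libraries from the relapse libraries with 1 AG120 library. For relapse minus vehicle the real split gave 16 and the highest other of 100 drawn 1. In each of the last 3 comparisons 1 split, the real one, gave as many genes, a share under 0.05. Most other splits put libraries of both groups on the same side, which widens the spread within a side and lowers the calls. The low counts of the other splits therefore do not exclude chance, and they say nothing about single genes.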

How the results depend on the processing

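Scaling by upper quartile, scaling by the total without ribosomal RNA, removal of its gene models and thinning were chosen only after the result was seen, and all other settings before. For named genes 11857 values kept their direction and side of the threshold, 780 lost their call and 12 gained one. Apart from 25 changes of sign in values not called, only H2-Eb1 in relapse minus AG120 turned, to −0.33 (adjusted p = 0.643) with AG120 day 14 alone as the comparison group, against 1.97. The count of genes for day 5 was 3710 to 6186 over the other settings, for day 14 3508 to 4888, for the mean 5218 to 7147 and for relapse minus AG120 5448 to 6528.

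The count for the difference between the days (112) was 374 with no filter, 869 with only the groups compared, 31 with limma-voom, 187 with DESeq2 and 53 with libraries thinned to 1259982 counts, where fewer counts were left. For relapse minus vehicle (22) it was 267 with no filter, 7 with only the groups compared, 120 with DESeq2, 6 with vehicle day 14 alone and 27 with vehicle day 5 alone as control. For vehicle day 14 minus day 5 (0) it was 33 with no filter and 236 with only the groups compared. With camera and a preset correlation, 12, 14, 15, 13, 14 and 5 lists were called for day 5, the mean, the difference between the days, relapse minus vehicle, relapse minus AG120 and vehicle over time, and with an estimated correlation 1 for the difference between the days and 0 for day 5, day 14, the mean and both relapse comparisons. The correlation of the mean effect with relapse minus vehicle (−0.110) was −0.244 for the day 5 effect and −0.0967 for the day 14 effect with split vehicle groups, where both the day and the controls differ. The cause was not tested beyond the settings' construction.

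Leaving out 1 library gave 3716 to 3873 genes at day 5, 2752 (without vehicle day 14 replicate 2) to 3003 at day 14, 5193 to 5785 for the mean, 13 (without AG120 day 14 replicate 1) to 61 for the difference between the days, 8 (without vehicle day 14 replicate 1 or 2) to 117 (without relapse replicate 2) for relapse minus vehicle, 5579 to 6514 for relapse minus AG120 and 0 for vehicle over time. Lists called were 18 to 23 at day 5, 13 (without vehicle day 14 replicate 1) to 17 at day 14, 25 to 27 for the mean, 2 (without AG120 day 14 replicate 2) to 7 for the difference, 0 (without vehicle day 14 replicate 1) to 6 (without relapse replicate 2) for relapse minus vehicle and 26 to 29 for relapse minus AG120. In these fits a lone library was assumed to vary like the other groups.

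The replicate numbers gave no clear pairing of the mice. At day 5 deviations of same-numbered libraries correlated at 0.107, 0.0491 and 0.0171, and those with different numbers at −0.106 to 0.0770. At day 14 the values were 0.0685 and −0.0685, which mirror each other by construction with 2 libraries per group. Pairing was thus neither shown nor excluded. With the number as a block, 4677, 4129, 6079, 108, 16, 6167 and 0 genes were called in the 7 comparisons, and 24, 21, 27, 6, 2, 27 and 0 lists.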

Other observations

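The genes given here were chosen only after their values were seen, and some lie outside the rule for named genes. Ngp was at 11.6 to 19.7 CPM in the 3 AG120 day 5 libraries and at 263 and 242 CPM in the AG120 day 14 libraries, against 61.8 to 70.1 in vehicle day 5 and 108 and 126 in vehicle day 14. Camp was at 2.18 to 5.03 CPM in AG120 day 5 and at 76.4 and 97.7 CPM in AG120 day 14, against 28.7 to 31.1 in vehicle day 5 and 35.7 and 57.1 in vehicle day 14. S100a8, a calprotectin subunit, was at 93.1, 67.9 and 114 CPM in AG120 day 5 and at 608 and 867 CPM in AG120 day 14, against 292 to 445 in vehicle day 5 and 510.4 and 634 in vehicle day 14. The list of secondary granule and neutrophil genes had a median difference between the days of 1.43, which did not pass by fry (adjusted p = 0.069).

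The 4 relapse libraries differed among themselves in stem cell and granule genes, given here per library with no grouping. In replicates 1 to 4, Sox4 was at 169, 608, 625 and 207 CPM, Meis1 at 84.8, 265, 137 and 78.5 CPM, Itga2b at 75.4, 247, 234 and 92.2 CPM, and Pf4 at 2.08, 18.9, 21.3 and 2.88 CPM. In the same order Mpo was at 1661, 403, 376 and 967 CPM, Itgam at 53.5, 13.9, 16.1 and 35.5 CPM, and Idh1 at 57.8, 21.0, 26.5 and 49.3 CPM. Cdkn2a was at 11.7, 18.7, 1.65 and 21.3 CPM. Ngp was at 23.0, 289.7, 29.7 and 18.5 CPM.

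Expression of Ptprc, which encodes the leukocyte antigen CD45, was 21.3% of its vehicle level at day 5 and 20.3% at day 14 under AG120, and that of Spi1, which encodes PU.1, was 20.4% and 10.0%. Sox4 was at 12.4% and 2.94% of its vehicle level and Mpo at 31.4% and 17.2%. Igf2bp3, lower in relapse, was at 80.0% at day 5 and 32.0% at day 14.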
